A study of Prunus domestica x Prunus domestica subsp. insititia with 6 samples.

How the data were processed

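Leaf RNA was sequenced from potted plum trees of the cultivar Julior, a cross of Prunus insititia and Prunus domestica that is used as a rootstock and is described in the labels as tolerant of flooding. The plants were 10 months old. Control plants were watered each day to field capacity, and flooded plants stood with water about 3 cm above the soil for 48 hours. The labels give 3 control and 3 flooded samples, numbered 1 to 3 in each group, and these numbers were used as the replicate numbers. The series' design text speaks of duplicates, which differs from the 3 labelled samples per group. The labels do not say whether the samples came from separate plants, so p-values measure the spread between these 6 samples, which can be technical.

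The deposited values are raw read counts per gene model, with 1 library per file and no normalization, as the whole numbers and the differing totals of the files show. Libraries were made with a TruSeq RNA version 2 kit, per the labels' protocols. The submitters' processing notes name FastQC 0.11.7, Trimmomatic, HTSeq 0.11.1 and edgeR 3.8, without saying in which step each was used. The aligner, the reference genome, the strand setting and the rule for reads that overlap 2 genes are not given in the sources used here. Nor do they give the species of the gene models, so whether reads of this hybrid were counted on plum genes or on those of another species is not stated. Values of near-identical gene copies, of overlapping genes and of antisense genes are uncertain. Each file lists 26873 gene IDs and 5 closing rows that name no gene. Those rows hold reads that fit no counted feature (0.940% to 5.63% of a library's listed reads), called reads outside gene models here. Which features were counted is not given, so these can include reads in introns or on the opposite strand. Those rows also hold reads that fit more than 1 gene model (2.49% to 2.71%) and reads aligned to more than 1 place (10.5% to 12.8%). The rows for unaligned and low-quality reads are 0 in all 6 libraries, so the share of reads that aligned is unknown. All 5 rows were left out of library sizes and tests.

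Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups (a minimum count of 10 and a minimum total of 15), which left 16917 genes. Library sizes were scaled by TMM factors, and groups were compared with edgeR's quasi-likelihood F test over all 6 libraries with no covariate. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Standard errors were taken from the fold change and its F statistic. Abundances are CPM (counts-per-million, scaled by the TMM factors) computed from the deposited counts, and log2 CPM used a prior count of 2. Single values per library were compared by exact two-sided permutation tests, which with 3 against 3 samples cannot give a p below 0.1. Binomial intervals are exact (Clopper-Pearson, 95%) and, like the limit of 3 counts for a gene without reads, cover counting error only.

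Total counts in genes ran from 11070986 to 15864206 per library, so that a gene with no read lies below 0.184 to 0.291 CPM, depending on the library. The test was checked on simulated counts for the comparison of flooding with control, drawn from the means, library sizes and spread of the 16917 genes, with 200 genes changed in each of 10 simulations. It recovered 14.2% of genes changed by 2-fold, 76.3% of those changed by 4-fold and 93.2% of those changed by 8-fold, and 6.58% of its calls were genes that had not been changed. With no gene changed, it called at most 1 gene. Genes were drawn independently of each other in these simulations. With fewer than 200 changed genes the adjustment is stricter, so recovery in the real data can be lower.

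The tests, the alternatives and the rule for named genes were chosen before the data were examined. The rule named genes by product, and 38 gene lists for leaf and flooding biology had been fixed by product name. The files do not pair the IDs with gene names, and no annotation was used here, so the lists and their camera and fry tests could not be run. The rule provides for this case: only the 2 called genes with the largest rise and the 2 with the largest fall are named by ID, among those with a mean of at least 1 log2 CPM whose groups do not overlap. No gene rose past the threshold, so the 2 genes above the controls in every flooded library with the smallest p are given instead, chosen after their values were seen. No function, symbol or position is given for any gene.

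The alternatives chosen at that stage were DESeq2 1.42.0 size factors, upper quartile factors or library totals in place of TMM, no filter or a filter of CPM above 1 in at least 3 libraries, DESeq2's Wald test, limma-voom (limma 3.58.1), edgeR's exact test, a threshold of 0.01, the replicate number as a block, and leaving out each library. After the data were seen, further fits left out both libraries that stood apart, used sample weights or robust dispersions, thinned all libraries to the smallest total, or removed the 20 most abundant genes.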

Results

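To measure how leaf transcripts of a plum described as flood tolerant differed after 48 hours of flooding, RNA was sequenced from leaves of 3 control and 3 flooded samples of the cultivar Julior. Reads counted in genes totalled 14747323, 15864206 and 13342964 in control replicates 1 to 3, a mean of 14651498 ± 1263350 (SD, n = 3). They totalled 11181094, 11070986 and 12578205 in flooding replicates 1 to 3, a mean of 11610095 ± 840213 (SD, n = 3). Every control library was deeper than every flooded one (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 samples can give). At least 1 read was found for 20901 ± 200 genes in control and 20689 ± 152 genes in flooded leaves (SD, n = 3 each). Of the 26873 genes listed, 3967 had no read in any library and 16917 had enough reads to be tested.

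After 48 hours of flooding, 5 genes fell and 0 rose past an adjusted p of 0.05 in edgeR's quasi-likelihood test. At an unadjusted p under 0.05, 720 genes were higher and 636 lower, in all 1356 or 8.02% of the tested genes. The 5 genes fell 3.94-fold to 9.17-fold, and in all 5 every flooded library lay below every control library. Their means were 36.0 to 958 CPM in control leaves and 3.92 to 138 CPM in flooded leaves, with at least 37 reads in each library. Of the 5, the largest fall was that of Prupe.2G256700, from 36.0 ± 11.3 CPM in control to 3.92 ± 0.712 CPM in flooded leaves (SD, n = 3 each), a log2 fold change of -3.20 (SE 0.27, edgeR adjusted p = 0.0369). Prupe.2G005900 fell from 156 ± 49.6 to 18.3 ± 3.41 CPM (SD, n = 3 each), a log2 fold change of -3.09 (SE 0.29, edgeR adjusted p = 0.0436). In the other 3 genes the log2 fold change ran from -2.80 to -1.98, with edgeR adjusted p of 0.0369 to 0.0381. The most abundant of them went from 958 ± 218 CPM in control to 138 ± 21.6 CPM in flooded leaves (SD, n = 3 each). Most fits with 1 library left out lost the calls. Without control replicate 1, control replicate 3 or any 1 of the flooded libraries, none of the 5 passed edgeR's test (adjusted p from 0.0571 to 0.269). Their log2 fold changes stayed between -3.37 and -1.89 in these fits, which also have fewer degrees of freedom. The losses thus do not show that 1 library carried the calls. Without control replicate 2 all 5 passed, among 26 higher and 96 lower genes. With the replicate number as a block, edgeR's test called 0 genes (adjusted p of the 5 genes 0.149). The labels do not say whether the numbers pair samples.

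**Figure D1:**
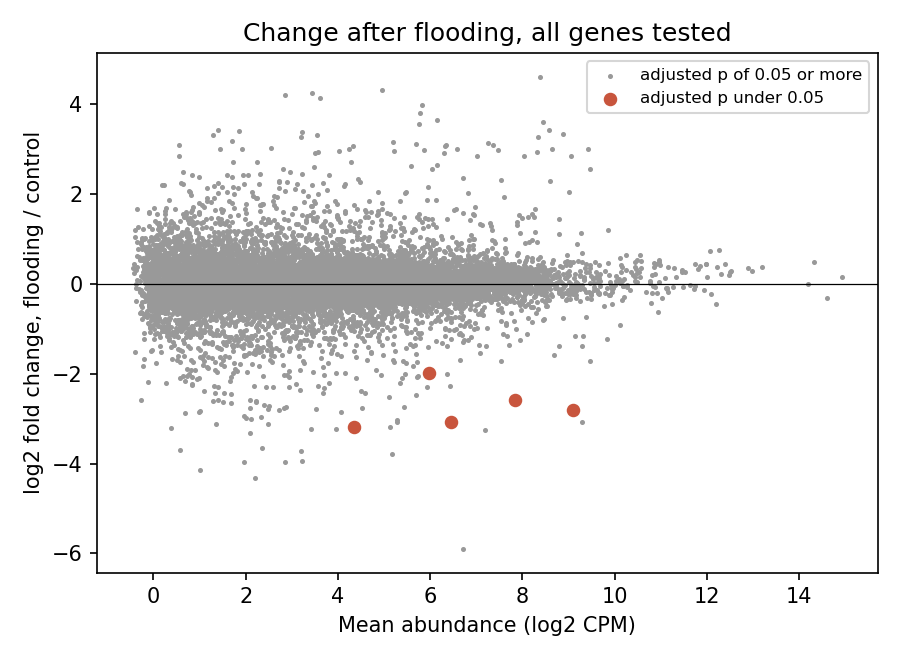
Log2 fold change (flooding over control, edgeR fit) against mean abundance in log2 CPM for the 16917 tested genes; each point is a gene and the larger red points are the 5 genes with an adjusted p under 0.05. All 5 lie below 0, between -1.98 and -3.20.

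In the upward direction, edgeR's quasi-likelihood test called 0 genes, limma-voom 0, DESeq2 108 and edgeR's exact test 64. The 2 genes nearest to the threshold of the first test, of those above the controls in every flooded library, were Prupe.1G339700 and Prupe.5G097700. Prupe.1G339700 had 44.1 ± 6.69 CPM in control and 121 ± 8.08 CPM in flooded leaves (SD, n = 3 each), a log2 fold change of 1.45 (SE 0.15, edgeR adjusted p = 0.0605). Prupe.5G097700 had 87.3 ± 3.03 CPM in control and 225 ± 30.8 CPM in flooded leaves (SD, n = 3 each), a log2 fold change of 1.36 (SE 0.16, edgeR adjusted p = 0.0680). DESeq2 called both, with adjusted p of 5.14e-13 and 3.65e-13. It called 233 genes in all, but up to 522 when the 6 libraries were split into 3 and 3 in other ways. Its small p-values alone therefore do not tie a gene to flooding. Over the other settings tried, the adjusted p of these 2 genes reached 0.463 and 0.489, both without control replicate 3. At an adjusted p under 0.1 in edgeR's test, 6 genes were higher and 17 lower.

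**Figure D2:**
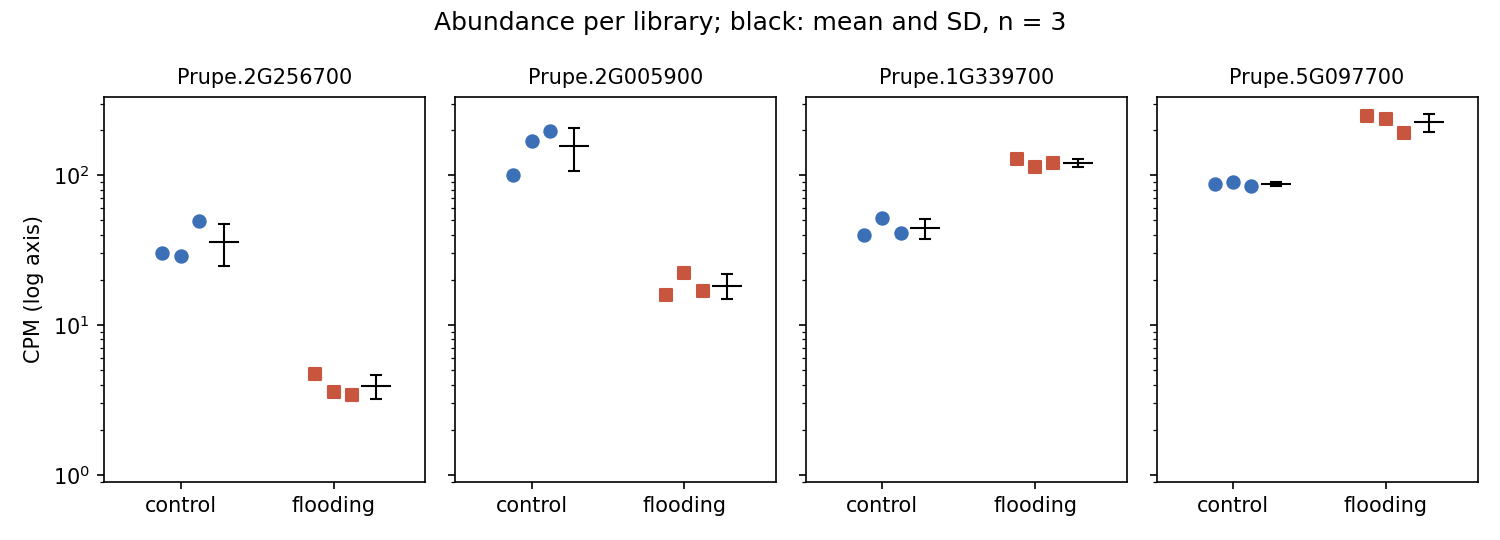
CPM on a log axis per library for the 2 called genes with the largest falls (left pair) and the 2 genes nearest to a called rise (right pair); blue circles are the 3 control and red squares the 3 flooding libraries, and black marks give the mean and SD. In all 4 genes the groups do not overlap, with means of 36.0 against 3.92, 156 against 18.3, 44.1 against 121 and 87.3 against 225 CPM.

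The number of called genes differed between tools. DESeq2, which used its own size factors and gave an adjusted p for 18055 genes, called 233 genes, 108 higher and 125 lower, and edgeR's exact test called 153, 64 higher and 89 lower. Both sets held the 5 genes, and 149 genes were shared by DESeq2 and the exact test. Limma-voom called 4 genes, all lower and all among the 5.

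Among abundant genes, with a mean of at least 5 log2 CPM, large fitted changes were mostly uneven between the libraries of a group. A fitted change of at least 4-fold was seen upwards in 38 such genes and downwards in 20. None of the 38 passed edgeR's quasi-likelihood test (smallest adjusted p = 0.339), while 23 had an unadjusted p under 0.05, DESeq2 called 7, edgeR's exact test 5 and limma-voom 0. In 31 of them flooding replicate 3 did not exceed the highest control. In 7 of the 38 all flooded libraries lay above all controls. Of the 20 lower genes, 3 passed, and in 10 all flooded libraries lay below all controls. In 9 of the 20, control replicate 2 was nearer to the mean of the flooded libraries than to that of the other controls. Among all tested genes with at least 1 log2 CPM whose groups did not overlap, the largest fitted fall belonged to a gene that was not called, singled out after its values were seen. It had 205 ± 41.4 CPM in control and 3.39 ± 2.54 CPM in flooded leaves (SD, n = 3 each), a log2 fold change of -5.90 (SE 0.66, edgeR adjusted p = 0.0680). Its reads numbered 2335 to 3937 in control and 6 to 66 in flooded libraries. DESeq2 (adjusted p = 1.66e-22), edgeR's exact test (3.72e-12), and edgeR's quasi-likelihood test without a filter (0.0300), without control replicate 2 (0.0272), without flooding replicate 2 (0.0347) or without both (0.00769) called it, as did limma-voom with sample weights (0.0250). Without control replicate 3 its adjusted p was 0.446, the highest of the fits tried. The limit given above for DESeq2's p-values applies here too.

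No difference in the 100 most abundant genes passed a test. The 10 most abundant genes took 13.4% ± 1.68 of gene counts in control and 14.1% ± 2.24 in flooded leaves (SD, n = 3 each; exact permutation p = 0.6). Their log2 fold changes ran from -0.30 to 0.49, with the groups overlapping in all 10 (smallest edgeR adjusted p = 0.809), and the 95% interval excluded a 2-fold difference for 1 of them. Of the 100 most abundant genes, 0 were called by edgeR's quasi-likelihood test, DESeq2, edgeR's exact test or limma-voom, and 0 had an unadjusted p under 0.05 in the first of these tests. The 95% interval of the change excluded a 2-fold difference in either direction for 54 of these 100 genes. Over all tested genes it did so for 11501 genes (68.0%), and it excluded a 4-fold difference for 15590 (92.2%). The median standard error of a log2 fold change was 0.23. In simulated data with this spread and 200 changed genes, drawn independently, 14.2% of genes changed by 2-fold were recovered. With fewer changed genes the adjustment is stricter, so recovery in the real data can be lower.

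Libraries of the same group were not always more alike than libraries of different groups. Across genes, which are not independent replicates, the correlation of log2 CPM was 0.935 to 0.978 between control libraries, 0.945 to 0.959 between flooded libraries and 0.933 to 0.960 between libraries of different groups. Control replicates 1 and 3 formed the closest pair (r = 0.978). Control replicate 2 lay nearer to flooding replicate 3 (r = 0.960) than to control replicates 1 (r = 0.935) and 3 (r = 0.957). This was not particular to control replicate 2. Flooding replicate 3 correlated slightly more with control replicates 1 (r = 0.9573), 2 (r = 0.9602) and 3 (r = 0.9592) than with flooding replicate 1 (r = 0.9569). Its correlation with flooding replicate 2 was lower still (r = 0.9448). The first principal component held 37.5% of the variance, and on it control replicate 2 (18.2) lay beyond flooding replicate 3 (-6.12), towards flooding replicates 1 (28.8) and 2 (49.4). The group accounted for 44.8% of the spread on the first component. The exact permutation p was 0.2 for the first component and 0.4 or more for the next 4, where 3 against 3 samples cannot give less than 0.1. The biological coefficient of variation was 27.1% among the control libraries and 28.3% among the flooded ones. Among controls it was 17.4% without control replicate 2, 27.1% without control replicate 1 and 34.8% without control replicate 3. All pairs of libraries differed by more than sampling noise, with a chi-square of at least 21.5 per gene, so none was treated as a library deposited more than once.

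**Figure D3:**
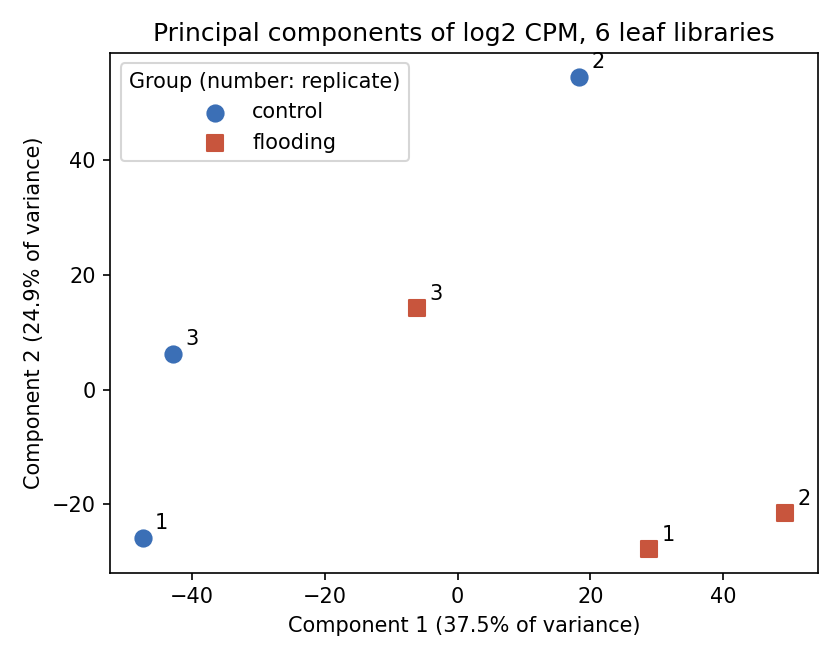
Principal components of log2 CPM over the 16917 tested genes; each point is 1 leaf library, blue circles are control, red squares are flooding, and the number is the replicate. Control replicate 2 lies at 18.2 on component 1, apart from control replicates 1 (-47.4) and 3 (-42.8), and flooding replicate 3 lies between the groups at -6.12.

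Groups did not overlap in 2181 of the tested genes (12.9%), 1143 higher and 1038 lower after flooding, where 3 against 3 samples give 10% by chance. The other 9 splits of the 6 libraries into 3 and 3 gave 717 to 2657 such genes, and 3 of them gave more than the real groups. With at least 3 reads in each library of 1 group and none in the other, 3 genes were seen only in flooded and 1 only in control leaves. The share of reads outside gene models was 1.19% ± 0.164 in control and 2.56% ± 2.66 in flooded libraries (SD, n = 3 each; exact permutation p = 0.9). Reads aligned to more than 1 place made up 10.9% ± 0.520 and 11.8% ± 0.960 (SD, n = 3 each; exact permutation p = 0.2).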

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

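Of the tests in this part, the one of genomic DNA was set before its result was seen, and the one that compared each flooded library with the highest control was chosen after. Reads outside gene models made up 5.63% of flooding replicate 2 (exact 95% interval 5.61% to 5.64%), against 1.19% ± 0.164 in the controls (SD, n = 3), more than 3 SD above their mean in data that the gene comparison does not use. The share was 1.11% and 0.940% in flooding replicates 1 and 3, so 1 of the 3 flooded libraries exceeded the highest control (1.37%). A rise in all flooded libraries was thus not seen. Since flooding replicate 2 was already known to be high, this comparison cannot exclude a response to flooding in that sample alone. Genomic DNA spread evenly over the genome would also add reads to nearly silent genes. In genes with 1 to 5 reads in the other 5 libraries, flooding replicate 2 had 1.37 times the depth-scaled reads of the median of the others, the highest of the 6 libraries (0.707 to 1.22 in the others) but below the 2 times set as the lower bound, which argues against such DNA as the whole cause. Reads from a few places outside the gene models, or within genes but outside the counted features, remain possible. They were not tested, since no genome was used here.

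Reads aligned to more than 1 place made up 12.8% of flooding replicate 1, also more than 3 SD above the controls (10.9% ± 0.520, SD, n = 3).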

How the results depend on the processing

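Lower genes numbered 5 and higher genes 0 in the reported fit. Size factors from DESeq2 in edgeR, the CPM filter, limma-voom, robust dispersions, thinning and removal of the 20 most abundant genes left both within 1.5 times of the reported counts (4 to 6 lower, 0 higher). Upper quartile factors gave 1 higher and 7 lower, library totals 1 and 9, and no filter 1 and 9. DESeq2 gave 108 higher and 125 lower, edgeR's exact test 64 and 89, and the threshold of 0.01 gave 0 and 0. Leaving out 1 library gave 0 to 26 higher and 0 to 96 lower, both maxima without control replicate 2, and no library but that one could be left out with a call of the 5 kept. Of the settings chosen after seeing the data (these, robust dispersions, thinning and removal of abundant genes), leaving out control replicate 2 and flooding replicate 2 gave 22 higher and 95 lower, and sample weights gave 8 and 19. Over 20 alternatives the 5 genes kept their direction in all 100 values (log2 -3.40 to -1.89) and their call in 69. Their adjusted p rose to 0.269 at most. The direction could hardly change, since in all 5 every flooded library lay below every control library. The 2 named genes that were higher passed under DESeq2, the exact test, sample weights and without control replicate 2; Prupe.1G339700 also passed with upper quartile factors, library totals, no filter and both libraries left out. Library totals moved the median log2 change of all genes to -0.08. With the replicate block no gene was called (0 higher, 0 lower; adjusted p of the 5 genes 0.149). The same-numbered samples deviated together with r = 0.06, 0.16 and 0.12; the first is under 0.1, so the numbers were not taken to pair samples, though each sample correlated best with its own number. The cause was not tested, except that fewer libraries or a block leave fewer degrees of freedom. The tests of the 38 gene lists and their alternatives were not run, since the files do not pair IDs with names. Thinning to the smallest total kept all 5 calls. At the spread between these libraries 14.2% of simulated 2-fold changes were recovered with 200 genes changed, and recovery with fewer changed genes can be lower.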

Other observations

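In this part, the tests of a mislabelled or swapped flooding replicate 3, of its reads, and of the splits for the 5 called genes, and the counts of genes set apart by 4-fold, were chosen after the results were seen. One set of genes was far above the controls in flooding replicates 1 and 2 and not in flooding replicate 3. In 28 genes, with a median of 5.21 CPM in control leaves, both of these flooded libraries exceeded every control at least 4-fold. The median difference from the control mean was 4.15 on the log2 scale in flooding replicate 1 and 3.30 in flooding replicate 2, but -0.94 in flooding replicate 3. Flooding replicate 3 was within or below the controls in 23 of the 28 genes, below all 3 controls in 18 of them, and at least 4-fold above them in 0. The other pairs of flooded libraries gave 0 such genes. Of the 28, edgeR's quasi-likelihood test called 0 (smallest adjusted p = 0.297), although 22 had an unadjusted p under 0.05; DESeq2 called 7, edgeR's exact test 5 and limma-voom 0.

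Falls were shared by the flooded libraries where these higher values were not. In 14 genes flooding replicates 1 and 2 were at least 4-fold below every control, and in 13 of them flooding replicate 3 was below every control too, in 9 by at least 4-fold. Taking every set of 1 or 2 libraries and every split into 3 and 3, the most genes set apart by at least 4-fold from the other libraries belonged to control replicates 1 and 3 together (38 higher and 14 lower). Flooding replicate 2 alone had 33 higher and 2 lower, control replicate 2 alone 0 higher and 24 lower, and the control group as a whole 9 higher and 0 lower.

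For the 28 genes, too few reads in flooding replicate 3 are argued against, since each gene would hold at least 42.9 reads there at the lower level of the other flooded libraries. Whether flooding replicate 3 is a mislabelled control plant stays open, because the values conflict. The position of flooding replicate 3 used the 100 genes that best parted the other 5 libraries, with controls at 0 and the other flooded libraries at 1. Its median was 0.191 (95% bootstrap interval -0.00085 to 0.344, over genes, which are not independent replicates). Flooding replicate 3 also correlated slightly more with each control than with either of the other flooded libraries. But flooding replicate 3 shared 13 of the 14 falls above, in 9 of them by at least 4-fold. Another control would be lowest in about 25% of genes taken at random. These 14 were chosen for high values in all 3 controls, so the share for another control would be higher and is not known. A difference between flooded samples in the extent or timing of the response may also account for the pattern, a hypothesis that was not tested.

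Control replicate 2 lay apart, with 122 genes called without it and 5 with it. Depth is argued against, since after thinning to the smallest total 122 genes were called without control replicate 2 and 6 with it. Once the 20 most abundant genes were removed, 121 and 5 were called, which argues against those 20 genes only. The 100 most abundant genes took 36.2% of gene counts in control replicate 2, against 28.6% and 30.5% in control replicates 1 and 3. In flooding replicates 1 to 3 they took 30.1%, 34.9% and 36.6%. Whether this wider difference played a part was not tested. A mislabelled flooded plant stays open. On the 100 genes that best parted the other 5 libraries, control replicate 2 lay at a median position of 0.980 (95% bootstrap interval over genes, not libraries, 0.921 to 1.13). This met the bound for a mislabelled flooded plant that was set before the result was seen. Simulated libraries gave 0.0647 if drawn as control and 0.951 if drawn as flooded, with 400 genes changed by 4-fold. Real libraries left out in this way did not all lie near these values, as given below. Control replicates 1 and 3 also had 38 genes higher and 14 lower than all other libraries by at least 4-fold. Such genes would also be seen if control replicate 2 were a flooded plant. But they can place any other library near 1, so the position does not decide the label. A swap with flooding replicate 3 also stays open, since with both labels exchanged 1972 genes had an unadjusted p under 0.05 against 1356 as labelled, but 0 were called against 5 and 7 were separated by at least 4-fold against 9. No biological explanation was tested, since the labels give control replicate 2 the same treatment as the other controls.

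The same position was 0.304 for control replicate 1, -0.0325 for control replicate 3, 0.837 for flooding replicate 1 and 0.793 for flooding replicate 2, so that of control replicate 1 was above that of flooding replicate 3. Of its 100 genes, control replicate 2 was nearer to the flooded libraries in 79, flooding replicate 1 in 77, flooding replicate 2 in 70 and flooding replicate 3 in 28. Several tests of flooding replicate 3 were tried. A further one took 72 genes at least 4-fold lower in flooding replicates 1 and 2 than in control replicates 1 and 3. Flooding replicate 3 lay below both those controls in 71 and control replicate 2 in 61. Chance would give 33.3% for genes taken at random, and more for these genes, which were chosen for high values in both controls. Each of these libraries was at the flooded level in 51. Control replicate 2 was at the control level in 15 and flooding replicate 3 in 3. In the 76 genes higher by the same measure, flooding replicate 3 lay above both controls in 39 and control replicate 2 in 69, but at the flooded level in 17 and 19 and at the control level in 42 and 21; the difference between the libraries was not tested.

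The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 5 called genes and the highest of the others 0, so 1 of 10 splits gave as many. For genes with an unadjusted p under 0.05 the real split gave 1356 and the highest other 1972, with 3 of 10 splits as large. For DESeq2 the real split gave 233 calls and the highest other 522, again with 3 of 10 as large. Both highest values came from control replicates 1 and 3 with flooding replicate 3 against the rest.

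Fold changes of genes with consecutive IDs were correlated over 11614 pairs (Spearman rho = 0.111, across genes, which are not independent replicates), against at most 0.0337 in 1000 shuffles. The test set before the result was seen asked whether the real split had the highest rho; 3 of the other 9 splits had one at least as high (0.116, 0.118 and 0.125), so with the labels as given it was not met. The highest of the 10 was the split with control replicate 2 and flooding replicate 3 exchanged, but all 10 lay between 0.0803 and 0.125, above the shuffles. Each of the other splits still holds part of the contrast between flooded and control libraries. The values above the shuffles therefore cannot tell flooding from another source.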
